A study of Homo sapiens with 6 samples.

How the data were processed

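Ribosome profiling was analysed in 6 libraries of WPMY-1, an immortalised line of human prostate stromal myofibroblasts. Ribosome profiling sequences the short stretches of mRNA that ribosomes shield from a nuclease, so a count per gene reflects both how much mRNA is present and how densely ribosomes sit on it. Per the labels, 3 libraries carried a control short hairpin RNA and 3 carried a hairpin against TRMT61A, the catalytic subunit of the methyltransferase that places 1-methyladenosine in tRNA. Per the labels' protocols, lysates were digested with RNase I, monosomes were taken from a sucrose gradient, adapters were ligated, ribosomal RNA was depleted and short footprints were selected on a gel before amplification. No molecular identifier is described, so copies of one molecule made by PCR may be counted more than once. Nothing in the labels says whether the libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

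The deposited table held raw read counts per Ensembl gene ID, 1 column per library, with no normalisation by the authors that the values show. Per the submitters' processing notes, fastp and Bowtie 1.3.1 were used with the hg38 build. The counting tool, the annotation, the read lengths kept and any removal of ribosomal or transfer RNA reads are not given in the sources used here. Most gene IDs end in a numeric suffix after the version, a form that GENCODE uses for annotation carried over to GRCh37, which differs from the build named in the notes. No coordinates are printed for this reason. Counts per ID do not show whether reads fell in coding sequence, an intron or a small RNA nested in the gene, and whether strand was used is not stated. Overlapping, antisense and near-identical genes are therefore uncertain. The 3 control columns are named for a vector and not for the control hairpin. They were matched to the control samples through the assay name and the replicate number, because the labels hold 2 groups and the other columns name the TRMT61A hairpin. The table has 6 further columns, named for RNA, for samples outside those described here, and these were not used. Without them a translational efficiency was not computed. A change in footprints is therefore not divided here into a change in mRNA and a change in its translation.

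The table holds 62492 features, of which 20515 had at least 1 count in the 6 libraries. The files do not pair IDs with gene names. The gene table used for names (assembly GRCh38.p14) has 59792 rows, none with an Ensembl ID, and 0 of the 62492 IDs matched any of its identifiers. Features are therefore called by ID. The level of TRMT61A in each library and the 27 gene lists fixed before the data were examined, TGF-beta signalling among them, were not analysed here. The rule for named features was also fixed before the data were examined. It took features past the adjusted threshold with a mean of at least 10 CPM over all 6 libraries and no overlap between groups, ordered by fold change. Its condition on gene symbols was dropped for want of names, and it was limited to 2 features in each direction. The 3 features with the largest mean share of counts in each group were named too. The parts of the rule that name genes by symbol or by list were not applied.

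Counts were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr, which left 11653 holding 99.8% of all counts. Libraries were scaled by TMM, and knockdown was compared with control over all 6 libraries by the quasi-likelihood F-test (glmQLFit and glmQLFTest, two-sided). The Benjamini-Hochberg adjusted threshold was 0.05. CPM values are TMM-scaled, and the standard error of a log2 fold change was taken as its size divided by the square root of F. The alternatives were DESeq2 1.42.0, other scaling factors, other count filters, limma 3.58.1 with voom, the replicate number as a block and each library left out in turn.

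Simulated counts for knockdown against control were drawn from the real means, depths and dispersions, with 200 features changed per run. At a 4-fold change, 54.3% of the 186 changed features that were tested (10945 tested in all) were recovered, with 3 false calls among 104. At a 2-fold change, 3 of the 181 changed features tested (10846 in all) were recovered, with 0 false calls. The real data had 1903 features at an unadjusted p under 0.05 in edgeR. With fewer changed features, all of 1 fold, the adjusted threshold was stricter in the simulation. These shares are therefore not recovery rates for the real data, where the smallest called change was 0.91 on the log2 scale. All recovered changes had the right direction. Total counts ran from 6771455 to 17752247 per library. A count of 0 allows up to 3 counts, which is 4.43e-05% of the shallowest library. Wilson 95% intervals of the largest single share in a library were at most 0.0652 percentage points wide. Such intervals and limits cover counting error only. Figures were drawn with matplotlib 3.10.9.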

Results

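Ribosome footprints were counted in 6 libraries of WPMY-1 prostate stromal cells, 3 with a control hairpin and 3 with a hairpin against TRMT61A. Control libraries 1 to 3 held 8008896, 6771455 and 7330168 counts, and knockdown libraries 1 to 3 held 17752247, 13284658 and 12704354. The mean total of the knockdown libraries was 1.98 times that of the control libraries. Despite the greater depth, the knockdown libraries detected 14318 ± 275 features (SD, n = 3) and the control libraries 14649 ± 173 (SD, n = 3), counting a feature with at least 1 count. The groups overlapped, since knockdown library 2 detected 14635 and control library 1 detected 14478, and this difference was not tested. IDs could not be paired with gene names, so the features below are given by Ensembl ID as deposited, and what each encodes is not stated.

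**Figure D1:**
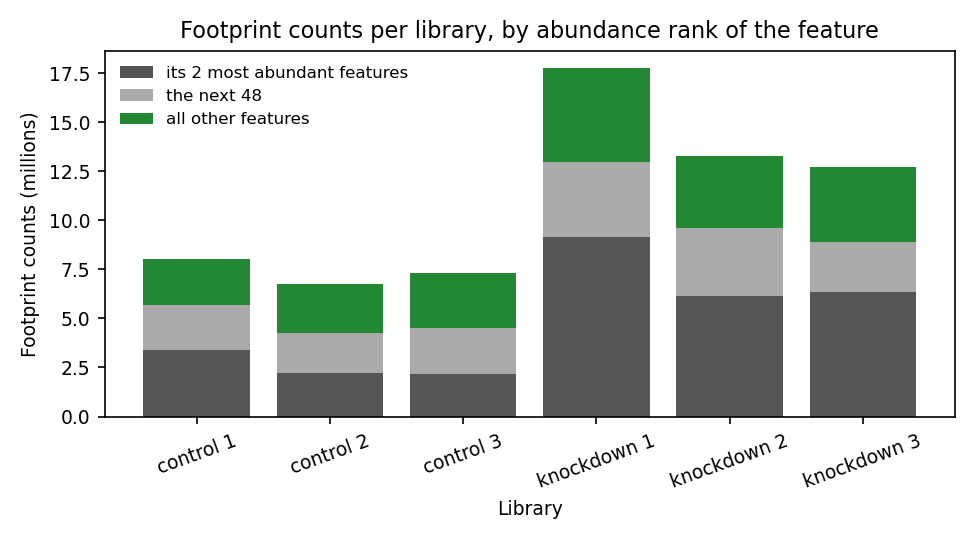
Footprint counts (y axis) for each of the 6 libraries (x axis), divided into each library's 2 most abundant features, the next 48 and all others. The 2 most abundant features alone hold between 29.9% and 51.6% of a library.

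Counts were concentrated on a few features in both groups. Counts per ID do not show whether these reads are footprints on coding sequence or come from an intron or a nested small RNA. The 50 most abundant features of a library held 65.2% ± 5.1 of the control counts and 71.8% ± 1.7 of the knockdown counts (SD, n = 3 each). Outside them, 2550641 ± 240617 control counts and 4093558 ± 579882 knockdown counts remained (SD, n = 3 each), a ratio of 1.60. ENSG00000234912.12_7 took 22.2% ± 9.5 of the control counts and 27.4% ± 12.9 of the knockdown counts (SD, n = 3 each). ENSG00000101361.17_6 took 12.9% ± 4.0 and 21.8% ± 13.1, and its share in single knockdown libraries ran from 7.93% to 33.9%. ENSG00000259001.3_7 took 3.51% ± 1.25 and 3.78% ± 0.31. ENSG00000261889.1_6 took 6.21% ± 1.51 of the control counts and 1.73% ± 1.18 of the knockdown counts. None of these 4 passed the test between groups in edgeR. Their log2 fold changes were 0.48 ± 0.45, 1.11 ± 0.48, 0.34 ± 0.36 and -1.52 ± 0.49 (SE), with adjusted p = 0.690, 0.271, 0.744 and 0.124. With 1 library left out at a time the log2 fold changes ran from 0.115 to 1.09, 0.605 to 1.54, 0.0683 to 0.832 and -2.14 to -1.08, so none of the 4 sizes was settled. The call for ENSG00000261889.1_6 depended on the method, since its adjusted p was 0.0298 with limma voom and 0.00123 in edgeR without the filter on low counts. The unfiltered fit also gave far smaller p-values, at nearly unchanged folds, for the features named below for the largest changes. ENSG00000101361.17_6 passed in 1 of 18 alternatives, the fit without knockdown library 3, at a log2 fold change of 1.54 and an adjusted p of 0.0375 in edgeR.

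The libraries varied widely within each group. Pearson's r of log2 CPM across the 11653 tested features was 0.840 to 0.879 between control libraries and 0.808 to 0.833 between knockdown libraries. Between groups it was 0.768 to 0.828, which overlaps the range within the knockdown group. These are correlations across features, which are not independent replicates. The first principal component carried 31.6% of the variance and separated the groups, from -73.5 to -41.1 in control and from 35.5 to 64.6 in knockdown. The second carried 22.5% and set knockdown library 1 (-79.6) apart from knockdown library 3 (77.5). The common coefficient of biological variation was 54.4%.

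The comparison the design implies is knockdown against control, and the series title and design text name translation, with the TGF-beta pathway, as its subject. Footprint counts of 364 features differed between the groups, 173 higher and 191 lower in the knockdown (edgeR quasi-likelihood test, adjusted p under 0.05), which is 3.12% of the 11653 tested. Of these, 166 rose and 181 fell by at least 2-fold, and 42 rose and 51 fell by at least 4-fold. The median log2 fold change was 1.57 among the features that rose and -1.63 among those that fell, against -0.0047 over all tested features. At an unadjusted p under 0.05 there were 1903 features, where chance alone would give about 583. With library size alone in place of TMM, 63 rose and 334 fell, and the median over all features moved to -0.30. The share of calls that rose was 47.5% with TMM and 15.9% with library size alone. The median near 0 and the balance of rises and falls therefore rest on the scaling. These counts cannot tell which balance is true.

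**Figure D2:**
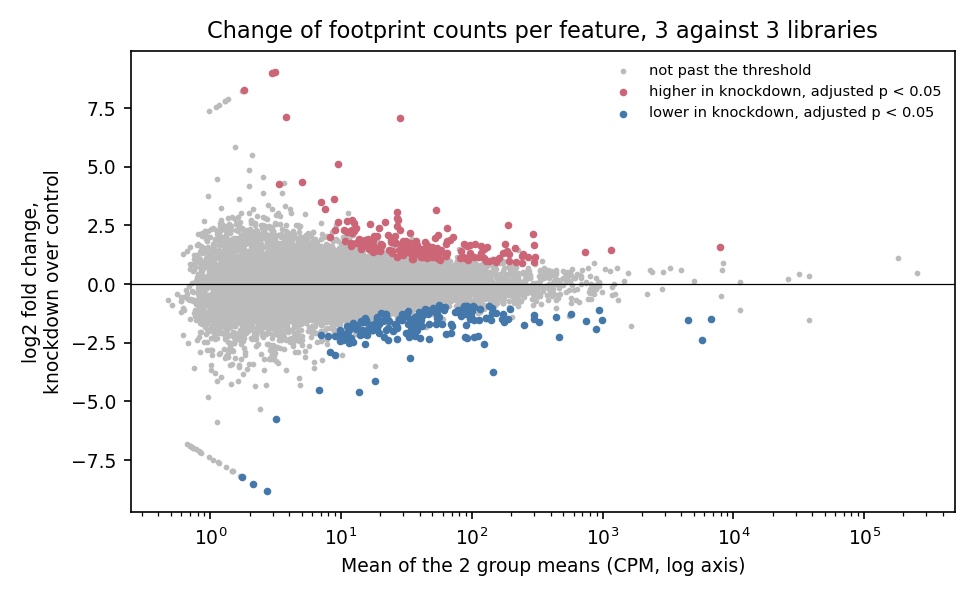
The log2 fold change of knockdown over control (y axis) against mean CPM on a log axis (x axis) for the 11653 tested features, 1 point each, where the diagonal rows at low abundance are features with no count in 1 group, whose fitted fold depends on the prior count. Coloured points are the 173 features higher and the 191 lower in the knockdown at an adjusted p under 0.05, and they lie mostly at higher abundance.

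In all 364 called features the 3 libraries of one group lay wholly above the 3 of the other. Features picked by a test on these same libraries tend to be separated, so this adds no support to the calls. Over all tested features 24.8% were separated in this way, where chance gives 10%. Calls rose with abundance. The most abundant 20% of the tested features, with a median of 489 counts per control library, gave 203 calls, which is 8.71% of them. The least abundant 20%, with a median of 14 counts, gave 5 calls. The median coefficient of variation within groups was 19.3% for control and 18.2% for knockdown in the most abundant 20%, and 69.2% and 87.3% in the least abundant.

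Among called features with a mean of at least 10 CPM over all 6 libraries, the rule for named features, the largest rise was that of ENSG00000171951.5_7. It had 0, 0 and 10 counts in the control libraries and 1102, 571 and 603 in the knockdown libraries, or 0.378 ± 0.655 CPM against 56.6 ± 13.8 CPM (SD, n = 3 each). Its log2 fold change was 7.09 ± 0.73 (SE), with an adjusted p of 0.0016 in edgeR. That fold rests on the 10 counts of control library 3. Without that library both remaining controls were at 0 and the fitted value, 12.28, depends on the prior count. Over the other alternatives it ran from 6.52 to 8.36, and it passed the threshold under all 19. ENSG00000059804.16_6 rose from 10.7 ± 3.9 CPM to 96.2 ± 13.8 CPM (SD, n = 3 each), a log2 fold change of 3.17 ± 0.32 (SE) and an adjusted p of 0.0016 in edgeR. It also passed under all 19 alternatives run for it, between 2.90 and 3.42 on the log2 scale.

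Among called features with a mean of at least 10 CPM over all 6 libraries, the largest fall was that of ENSG00000178977.3_5, from 26.3 ± 16.3 CPM in control to 1.03 ± 1.06 CPM in knockdown (SD, n = 3 each). Its log2 fold change was -4.62 ± 0.79 (SE), with an adjusted p of 0.0123 in edgeR. It missed the threshold in limma voom (adjusted p = 0.104). It also missed it without control library 2, control library 3 or knockdown library 2, at adjusted p = 0.0718, 0.0910 and 0.0791 in edgeR. ENSG00000221585.1 went from 34.3 ± 14.8 CPM to 1.90 ± 3.08 CPM (SD, n = 3 each), a log2 fold change of -4.11 ± 1.00 (SE) and an adjusted p of 0.0479 in edgeR. Its call was lost under 8 of 17 alternatives. These were DESeq2 (0.122), limma voom (0.0709), edgeR's robust fit (0.125) and 5 of the fits that left out a library, with adjusted p up to 0.182. Its knockdown counts were 83, 3 and 0, and without knockdown library 1 its log2 fold change was -7.96 (adjusted p = 0.00677 in edgeR). Without that library the value of ENSG00000178977.3_5 was -5.80. The direction of both features was the same under each alternative run, which the lack of overlap between their groups all but fixed in advance.

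**Figure D3:**
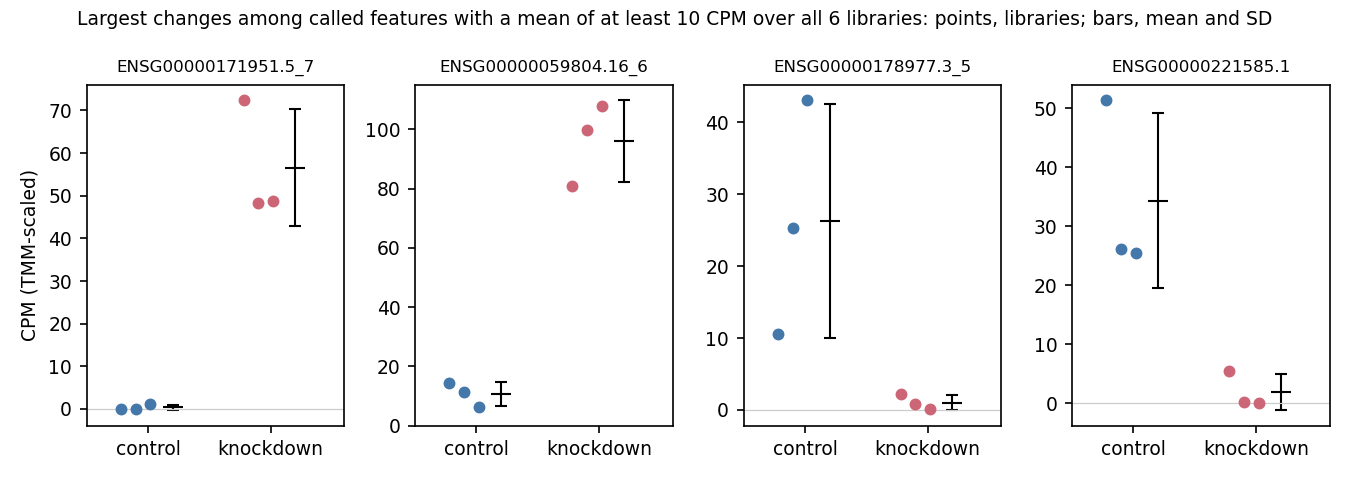
TMM-scaled CPM (y axis) of the 4 features named for the largest changes at a mean of at least 10 CPM over all 6 libraries, in 3 control and 3 knockdown libraries (x axis). Points are libraries and the bars beside them give the mean and SD. In each panel the libraries of the 2 groups do not overlap, which the rule for named features required.

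The count of calls fell whichever library was left out. Each such fit also has fewer samples, so the fall cannot be laid to particular libraries. Leaving out 1 library left 138, 47 and 77 calls without control libraries 1, 2 and 3. It left 167, 83 and 171 without knockdown libraries 1, 2 and 3. Of the 364 features, 35 were called in all 6 of these fits, 240 in at least 1 and 124 in none. No called feature changed direction in any of them. That was all but fixed in advance, since the groups of every called feature did not overlap.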

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

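Each of the 364 calls kept its direction under every alternative that tested it. The groups did not overlap in any of the 364, so this was all but fixed in advance and adds no support. The number of calls did not hold. The count came to 799 in DESeq2 (389 higher, 410 lower, with 4517 adjusted p-values undefined), and 351 of the 364 were among them. It was 735 without a filter on low counts (358 higher, 377 lower, all 364 included) and 602 with at least 10 CPM in 3 samples (287 higher, 315 lower, 348 included). In edgeR without the filter, ENSG00000171951.5_7 had an adjusted p of 5.57e-47 at a log2 fold change of 7.11. The main edgeR fit gave it 0.0016 at 7.09. P-values of the unfiltered fit are therefore far smaller at like folds, and its 735 calls should not be read beside the others. With library size alone 63 were higher and 334 lower, and 254 of the 364 remained. The replicate block left 208 (99 higher, 109 lower), of which 199 were among the 364. Deviations from the group means of same-numbered libraries correlated at -0.0065, -0.015 and 0.039, and not every library correlated best with its own number. These values show no pairing by number, but with 3 libraries per group they cannot exclude one. Leaving out 1 library at a time gave 47 to 171 calls, 22 to 86 higher and 25 to 85 lower. A fit without 1 library has fewer samples, and the filter then lets more features in. Requiring at least a 2-fold change kept 347. RLE and upper quartile factors, limma voom and removal of the 50 features most abundant over all 6 libraries gave between 356 and 443. So did thinning, the robust fit and removal of IDs without a suffix. The last 3 of these were added after seeing the data, as was leaving out features at 0 in 1 library and 30 or more counts in another of the same group. That last setting gave 551 calls (267 higher, 284 lower, 363 of the 364 included). The causes of these differences were not tested. The alternatives foreseen for TRMT61A, the gene lists and genes chosen by symbol were not run, since no ID could be named. Mitochondrially encoded genes were not removed for the same reason. In the simulated 4-fold changes, 46 of the 49 changed features among the most abundant 20% were recovered, against 101 of 186 at any abundance. Whether depth or the spread between libraries limits calls at low abundance was not tested.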

Other observations

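Of the tests in this part, that on the cell-cycle sets and the count of features seen in 1 group were chosen after their results had been seen.

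A set of 25 features had no count in any library of one group and at least 10 counts in every library of the other. Of these, 12 were seen only in the knockdown libraries and 13 only in the control libraries, and 6 of the 25 were among the 364 calls. The 9 other ways of dividing the 6 libraries into 3 and 3 gave 9 to 17 such features, so such counts also arise between mixed groups. For the count of changed features, the real grouping gave 364 and the highest of the other splits gave 0. Only 1 of the 10 splits, the real grouping itself, reached that count, and 10 splits are too few for a share under 0.05. Each other split has control and knockdown libraries on both sides, so any group difference adds to the spread within a side. Few calls were therefore likely there in advance, and the 0 gives the real count no support.

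Knockdown libraries disagreed with each other more often than control libraries about whether a feature was there at all. At full depth 1241 features had 0 counts in 1 knockdown library and 30 or more in another, against 263 among the control libraries. Greater depth of the knockdown libraries does not account for the whole excess. Each library was thinned to 2344622 counts outside the 50 features with the most counts over all 6 libraries. The ratio was then at least 2.13 in each of 20 thinnings, against 4.72 at full depth. Every pair of knockdown libraries still had more such features than every pair of control libraries. After thinning, each knockdown library detected at least 252 fewer features than the control library with the fewest. That number counts the same zeros, so it does not decide whether fewer distinct molecules stood behind the knockdown libraries. This and real differences between the cells behind the knockdown libraries both stay open.

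Features whose ID carries no numeric suffix after the version changed more often than the rest. Of 409 tested, 35 were called (8.56%, 12 higher and 23 lower in knockdown), against 329 of 11244 with a suffix (2.93%). Their share of all counts was 11.7% ± 2.6 in control and 8.98% ± 0.52 in knockdown (SD, n = 3 each). A higher abundance of these features is not enough to account for this. The common odds ratio over 10 abundance bins was 3.16 (exact 95% interval 2.08 to 4.69), against 3.10 with no bins. What these IDs encode is not known from the files, no biological explanation was tested, and features are not independent replicates.

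The cell-cycle marker pairs that come with the R package scran are given as Ensembl IDs and can be used without names. Genes that only ever mark the higher side of a pair made 3 sets, for G1, S and G2/M. The hypothesis that the knockdown changed the share of cells in a phase was left undecided. Of 110 tested G1 genes, 0 rose and 3 fell, with a median log2 fold change of -0.15 (bootstrap 95% interval -0.29 to -0.015). Of 113 S genes, 1 rose and 1 fell, with a median of 0.045 (-0.18 to 0.15). Of 108 G2/M genes, 1 rose and 5 fell, with a median of -0.018 (-0.22 to 0.14). Camera gave adjusted p = 0.216, 0.980 and 0.417 for the 3 sets in that order, and 0.478, 0.985 and 0.478 with an estimated correlation. The smallest of these, 0.216, is short of the threshold. The bootstrap resampled the genes of a set as if they were independent, so its intervals leave out the spread between libraries. For this reason the G1 interval cannot decide on a shift, although it lay below the median of features outside the 3 sets, -0.0038. The S and G2/M intervals are too wide to exclude a small shift. Adjusted over the list alone, 0 rose and 3 fell in G1, 2 rose and 4 fell in S, and 4 rose and 8 fell in G2/M. The directional fry test gave 0.0902, 0.727 and 0.103 after adjustment. Fry's mixed test, which asks whether genes of a set change in either direction, gave adjusted p = 0.000135, 4.7e-05 and 6.68e-05. It does not compare a set with other genes, so it does not single out these sets.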
